A study of Physcomitrium patens with 26 samples.

How the data were processed

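The series measured gene expression in protonemata of the moss Physcomitrium patens on 26 one-colour (Cy3) Agilent arrays, which fall into 14 groups of genotype, dose and time. Each array held 35359 spots, of which 1417 were controls and 33942 were probes of 60 nucleotides for predicted gene models. The deposited scanner files were made, per the file headers, by Agilent Feature Extraction 9.1.3.1 with the protocol GE1-v5_91_0806 on array design 021569. Their processed signal is an intensity on a linear scale which, per the file headers, the authors' software had corrected for background and for spatial and multiplicative trends within each array, with surrogate values for spots near background and with no scaling between arrays. The deposited mean spot signal and median local background are pixel intensity values without normalization. Other deposited columns are 0 or 1 flags of another kind, among them whether a spot was well above background, saturated or an outlier. The deposited series matrix also held intensity values, and these were checked to be the processed signal rounded, with a largest difference of 0.5%.

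Names of genes came from the array files alone, because 0 of the 33942 models were found in the reference gene table. A description by eukaryotic orthologous group (KOG) was present for 14455 probes (42.6%), in 3493 such groups. KOG names often come from animal or fungal proteins and stand here for sequence similarity.

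Processed signals were log2 transformed and the 75th percentile of the non-control probes of each array was subtracted. Spots marked as outliers by the authors' software were left out as missing values. A probe was tested if it was well above background on all arrays of at least 1 group of the comparison. Models were fitted with limma 3.58.1 in R 4.3.3, with moderated two-sided tests without a trend, and p-values were adjusted by the Benjamini-Hochberg method over all probes tested. An adjusted p under 0.05 was the threshold, and calls with at least a 2-fold change were counted beside it. Tables and figures were prepared with python 3.11.15. The p-values measure only the spread between these arrays.

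The 1 µM comparison used 6 arrays (4 residual degrees of freedom). The 4 genotypes at 0 h were fitted together on 12 arrays (8 residual degrees of freedom), and the double disruptant was also set against the sum of both single disruptants. For 10 µM ABA, each genotype and time had 1 array, so the 4 times of a genotype were fitted as 1 group against its 3 arrays at 0 h (14 arrays, 10 residual degrees of freedom). The change over time thus entered the residual, and values per time carry no test. Both genotypes under 10 µM were compared in 4 pairs matched by time. Both sets of untreated wild type were compared with each other. The direct comparison of ppabi1a with ppabi1b and its alternatives were added after the data were seen.

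Replicate numbers were checked for pairing across genes. In the first experiment deviations of arrays with the same number correlated by r = 0.71, 0.65 and 0.74, so these arrays pair. In the second, arrays with the same number as wild type correlated with it by 0.11 to 0.23 in ppabi1b and 0.10 to 0.22 in ppabi1a/b, over 0.1 for every pair and so taken as paired, and by −0.21 to 0.30 in ppabi1a. The files showed 8 slides and 4 scan days. Slides 1 to 3 each held 1 replicate of the untreated and of the 1 µM wild type and were scanned on separate days. Slides 4 to 6 each held 1 replicate of all 4 genotypes at 0 h, slide 7 the 4 treated wild-type arrays and slide 8 the 4 treated ppabi1a/b arrays, all scanned on 1 day.

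Before the data were examined, the comparisons, 23 gene lists, the rule for named genes and most alternatives were fixed. Of these lists, 13 matched the KOG names after their patterns had been restricted to the name of the group: protein phosphatases 2C (KOG0700), heat shock proteins and chaperones, antioxidant enzymes, trehalose-6-phosphate synthases and invertases, chlorophyll and haem synthesis, cytosolic ribosomal proteins, histones, cyclins and replication, bZIP factors, aquaporins, cytochromes P450, tubulins, and MADS box factors, which stand for regulators of other tissues than protonemata. Lists for proteins of late embryogenesis, ABA core signalling, oleosins, early light-induced proteins, photosystems, organelle ribosomes, expansins, AP2/ERF and WRKY factors and lipid transfer proteins had no usable match and were not tested. A further 21 lists were written after the annotation but before any expression value was seen. All 34 lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. The 24 KOG functional classes were tested likewise. fry tests whether a set's genes move, on balance, one way and does not compare them with other genes. A list needed at least 5 tested members. Genes that changed at least 2-fold with 1 µM ABA were tested as lists in the other comparisons, in a planned family of 6 tests (both lists in the 3 disruptants at 0 h) and a family of 14 further tests.

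Named genes are, per comparison, the 12 largest rises and 12 largest falls with a KOG name among calls of at least 2-fold whose groups did not overlap, with 1 probe per gene and uncharacterised proteins passed over. To these were added the 4 members of each list with the smallest p in the 1 µM, 10 µM and ppabi1a/b comparisons and the models taken for PpABI1A and PpABI1B. Where a group lay below background on all its arrays, the fitted change is no measurement and a bound is given as at least N-fold. It is the brighter group's mean against the dim group's mean of, on each array, the higher of the probe's own value and the lowest signal among probes well above background, all on the normalized log2 scale. Principal components were computed over 14960 probes that were well above background on all 26 arrays.

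The model was tested on simulated data with the spread and size of 5 of the comparisons and 100 changed genes for each size of change. A 4-fold change was recovered for 57 genes in the 1 µM comparison, 89 in ppabi1a/b at 0 h, 77 in wild type under 10 µM ABA, 62 between genotypes under ABA and 68 between the untreated sets. For a 2-fold change the numbers were 0, 75, 65, 21 and 18. Between 2 and 12 unchanged genes were called in these runs, and 0 in runs without any change.

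Alternatives tried were normexp background correction (offset 50), quantile normalization, centring on the median, no filter, a filter on every array, the series matrix values, a trended and robust prior variance, the replicate number as a block, the slide as a random block, fits of only the 2 groups compared, each replicate or time left out, all 6 untreated wild-type arrays as the 0 h group, no time block, camera with an estimated correlation, fry, and the 1 µM lists without the 2-fold minimum. A count was taken as unchanged within a factor of 1.5. Chosen after the data were seen were the 1 µM comparison without slide 1, the lists from that fit and from the fit with the replicate block, and the 10 µM comparisons with 6 h and 12 h only.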

Results

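Expression was measured in one-week-old protonemata, the filamentous stage of the moss Physcomitrium patens, with and without abscisic acid (ABA), a plant stress hormone. A first experiment held untreated wild type and wild type after 3 h of 1 µM ABA, with 3 arrays each. A second experiment held wild type, both single disruptants ppabi1a and ppabi1b and the double disruptant ppabi1a/b at 0 h, with 3 arrays each. It also held wild type and ppabi1a/b at 1, 3, 6 and 12 h of 10 µM ABA, with 1 array per genotype and time and so no replicate of a time. The 75th percentile of signal ranged from 1239.9 to 3008 intensity units between arrays. Of 33942 probes 17528 to 21503 were well above background, the lowest numbers being 17528 and 17601 in wild type at 1 h and 3 h of 10 µM ABA. The number of arrays limits the precision. Changes below are log2 differences ± the standard error of the limma model with its adjusted p, between means of 3 arrays per group at 0 h and at 1 µM and of the 4 times under 10 µM, unless stated. Names are those of KOG groups, and models without such a name stay unnamed. A name was available for 45.7% of the genes that changed at least 2-fold with 1 µM ABA, 36.4% of those in ppabi1a/b at 0 h and 52.2% of those in wild type with 10 µM ABA, against 59.0%, 58.9% and 59.4% of the probes tested.

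The first principal component of 14960 probes held 45.3% of the variance. Untreated wild type of the second experiment lay lowest on it, between −70.05 and −67.06, followed by ppabi1b (−60.42 to −53.68), ppabi1a (−36.85 to −33.68) and ppabi1a/b (−9.67 to 6.66). Wild type under 10 µM ABA lay higher with each time after 1 h (89.79 at 3 h, 100.06 at 6 h and 114.46 at 12 h), and ppabi1a/b under the same dose lay between 14.03 and 39.54. Untreated replicates 1 to 3 of the first experiment lay at −53.11, −7.47 and −18.85.

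**Figure D1:**
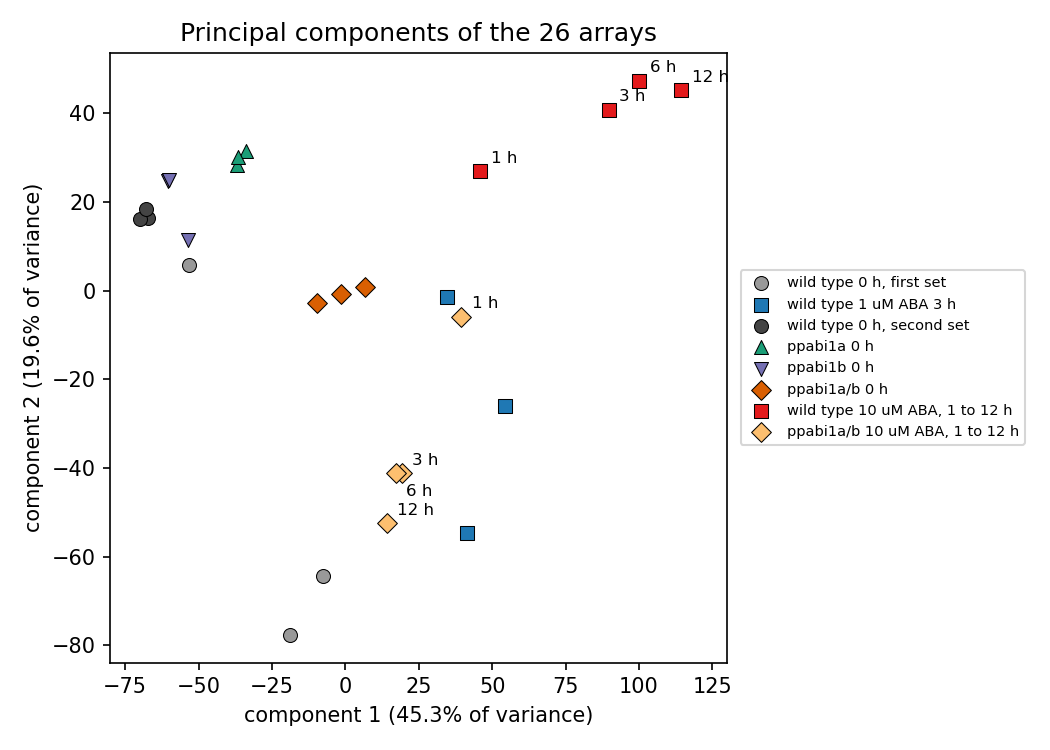
First against second principal component of the 26 arrays (scores without unit), 1 point per array, with hours of ABA written beside the arrays of the 10 µM series. Wild type under 10 µM ABA reaches 114.46 on the first component, and ppabi1a/b at 0 h lies between −9.67 and 6.66.

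The disrupted genes are not named in the array annotation, so the serine/threonine protein phosphatases of KOG0698, the group that holds phosphatases of the 2C type, were read for models lost in a disruptant. Of 36 such models well above background in wild type at 0 h, ppabi1a lost 1, gw1.311.62.1, ppabi1b lost 1, gw1.80.44.1, and ppabi1a/b lost both. Model gw1.311.62.1 had a mean normalized log2 signal of −0.16 ± 0.11 (SD, n = 3) in wild type and was not well above background on any array of ppabi1a or ppabi1a/b, at least 89.4-fold and 97.2-fold lower. Model gw1.80.44.1 had a mean of 2.09 ± 0.06 (SD, n = 3) in wild type and was at least 336-fold lower in ppabi1b and at least 462-fold lower in ppabi1a/b. In the other single disruptant each remaining model was higher than in wild type, gw1.80.44.1 by 0.64 ± 0.10 in ppabi1a (adjusted p = 0.00252) and gw1.311.62.1 by 0.49 ± 0.15 in ppabi1b (adjusted p = 0.0493). Both models rose in wild type with ABA. Model gw1.311.62.1 rose by 1.92 ± 0.26 at 1 µM (adjusted p = 0.0243, 2 treated arrays with a value) and 3.35 ± 0.17 at 10 µM (adjusted p = 5.03e-08), and gw1.80.44.1 by 1.74 ± 0.32 (adjusted p = 0.041) and 2.75 ± 0.16 (adjusted p = 1.53e-07). Under 10 µM ABA they stayed below background in ppabi1a/b, at least 1090.0-fold and 3425-fold lower than in wild type. Where these probes lie relative to the disrupted part of each gene is not known. The same loss of signal was met by 25 probes in ppabi1a, 25 in ppabi1b and 46 in ppabi1a/b.

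**Figure D2:**
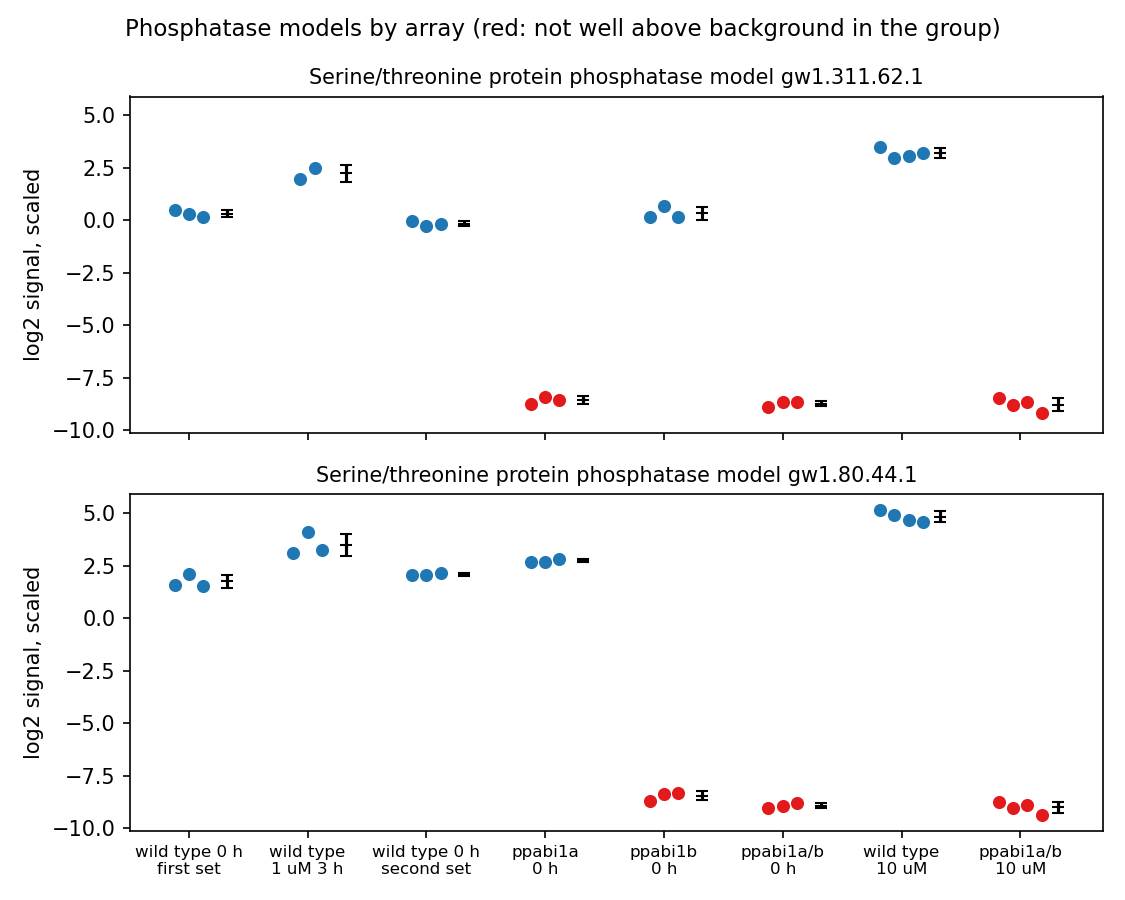
Normalized log2 signal of both phosphatase models on every array (points; red where the group is not well above background), with mean and SD of each group. gw1.311.62.1 falls from a mean of −0.16 in wild type at 0 h to −8.58 in ppabi1a, and gw1.80.44.1 from 2.09 to −8.46 in ppabi1b.

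After 3 h of 1 µM ABA, the comparison meant to find early ABA-responsive genes, more genes rose than fell in wild type. The largest named rises were a fasciclin-related adhesion glycoprotein (estExt_gwp_gw1.C_320117, 9.36 ± 1.61, adjusted p = 0.0319), a WASP-interacting protein (estExt_fgenesh1_pg.C_1410087, 9.02 ± 1.36, adjusted p = 0.0211) and a Zn-finger protein (estExt_Genewise1.C_2110049, 8.88 ± 1.70, adjusted p = 0.0464). An endoplasmic reticulum membrane protein (estExt_gwp_gw1.C_600001, 8.88 ± 0.65, adjusted p = 0.00324) and a sorbitol dehydrogenase (e_gw1.65.263.1, 8.85 ± 1.48, adjusted p = 0.0291) came next. A phospholipase C specific for glycosylphosphatidylinositol (estExt_Genewise1.C_1550075) rose by 8.77 ± 1.42 and a reductase (e_gw1.6.137.1) by 8.44 ± 1.62. Untreated, these 7 were well above background on only 1 or 2 of 3 arrays, so the sizes rest on signal near background. A stress responsive protein (estExt_Genewise1.C_710089) rose by 7.36 ± 1.13 and a lipid phosphate phosphatase (e_gw1.4.391.1) by 6.87 ± 0.46. Among the falls were an isoaspartate methyltransferase (estExt_gwp_gw1.C_550109, −3.32 ± 0.62, adjusted p = 0.0425) and an invertase, which splits sucrose (estExt_fgenesh1_pm.C_660005, −2.53 ± 0.47, adjusted p = 0.0412). A carbonic anhydrase (estExt_Genewise1.C_300133, −2.39 ± 0.43) and an inositol monophosphatase (estExt_Genewise1.C_2750013, −1.52 ± 0.23) fell as well.

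By group, 4 of 64 antioxidant enzymes rose with 1 µM ABA and 0 fell (6 and 1 adjusted over the list alone). Among them were 2 catalases, which break down hydrogen peroxide (e_gw1.3.315.1, 4.21 ± 0.53; fgenesh1_pg.scaffold_223000044, 3.94 ± 0.38), and a glutaredoxin (gw1.42.246.1, 4.30 ± 0.43). Of 36 phosphatases of KOG0698, 4 rose and 1 fell (4 and 1 adjusted over the list alone), with 3.75 ± 0.45 for estExt_fgenesh1_pg.C_930093 (adjusted p = 0.00959) and a fall of e_gw1.304.15.1 (adjusted p = 0.026). Of 69 lipases and phospholipases 10 rose and 0 fell (12 and 1 adjusted over the list alone). Examples are a lysophospholipase (fgenesh1_pm.scaffold_100000002, 2.71 ± 0.24) and 2 phospholipases D (estExt_Genewise1.C_940006, 2.22 ± 0.27; estExt_gwp_gw1.C_20288, 1.86 ± 0.22). This list ranked higher than other genes (adjusted p = 0.0326, and adjusted p = 0.921 with an estimated correlation), with a mean of 0.32 and a median of −0.01 that turned to 0.06 under median centring. With the replicate as a block, which the pairing of these arrays calls for, the list was no longer called (adjusted p = 0.0818). The 19 small heat-shock proteins ranked higher as well (median 0.65, adjusted p = 0.00779, and adjusted p = 0.921 with an estimated correlation), also with the block (adjusted p = 0.0157). Over all genes limma called 0 of them, 6 passed at an unadjusted p under 0.05 and 2 when adjusted over the list alone. Of the receptor-like kinases 6 of 241 rose and 1 fell (6 and 1 adjusted over the list alone, median −0.27), with 5.04 ± 0.43 for gw1.112.139.1. Of 51 two-component histidine kinases 3 rose (3 adjusted over the list alone), the largest being e_gw1.51.2.1 at 2.89 ± 0.22.

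In the whole set 651 of 19173 probes changed, 570 up and 81 down, of which 563 and 78 at least 2-fold. The count rests on few arrays. It was 253 without replicate 3 of the untreated arrays and 277, 161 and 371 without replicate 1, 2 or 3 of the treated ones. With the replicate as a block it was 1691, including 648 of the 651, and the excess of rises was smaller, with 1069 up and 622 down (862 and 336 at least 2-fold) and so 63.2% in place of 87.6% of calls up. Without a filter on dim probes it was 304. Of the 24 genes named by the size of their change, 20 lost the threshold without replicate 3 of the untreated arrays, 19, 22 and 18 without replicate 1, 2 or 3 of the treated ones, 19 without the filter and 0 with the replicate block.

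In ppabi1a at 0 h, the genes that stood highest over wild type were for the most part those just named. The fasciclin-related gene was at least 315-fold higher, the Zn-finger gene at least 146-fold, a myosin-related gene (fgenesh1_pg.scaffold_15000002) at least 135-fold and the WASP-interacting gene at least 88.0-fold. The phospholipase C was at least 32.1-fold and a cation channel (estExt_fgenesh1_pg.C_130174) at least 26.5-fold higher, and all 6 were not well above background in wild type. The reductase e_gw1.6.137.1 was higher by 7.72 ± 0.51 (adjusted p = 8.83e-06), a small heat-shock protein (e_gw1.144.75.1) by 7.40 ± 0.43 (adjusted p = 3.72e-06) and a gene related to meiotic chromosome segregation (e_gw1.2.84.1) by 6.07 ± 0.34. Lower in ppabi1a were, after the lost phosphatase model, 6 transposon-encoded proteins, such as fgenesh1_pg.scaffold_146000003 (−5.11 ± 0.72) and fgenesh1_pg.scaffold_98000103 (−3.65 ± 0.27). An aquaporin, a channel for water (e_gw1.118.8.1, −3.27 ± 0.48, adjusted p = 0.00178), and a ribokinase (estExt_fgenesh1_pm.C_220016, −2.66 ± 0.21) were lower too.

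Among the lists, ribosomal proteins were lower by a small amount in ppabi1a (53 of 393 lower, 3 higher; 14 and 1 adjusted over the list alone, median −0.12, adjusted p = 5.36e-06, and adjusted p = 0.814 with an estimated correlation). Tubulins (6 of 19 lower, 15 adjusted over the list alone, median −0.18, adjusted p = 0.000959) and cyclins and replication proteins (23 of 81 lower, 2 higher; 28 and 4 adjusted over the list alone, adjusted p = 0.0217) were called lower, each with adjusted p = 0.814 with an estimated correlation. So were proteasome subunits (11 of 81 lower, 1 higher; 6 and 0 adjusted over the list alone, adjusted p = 0.0217, and adjusted p = 0.814 with an estimated correlation) and aminoacyl-tRNA synthetases (7 of 47 lower; 6 adjusted over the list alone, adjusted p = 0.0321, and adjusted p = 0.841 with an estimated correlation). Transposon-encoded proteins were lower for 11 of 26 and higher for 3 (12 and 4 adjusted over the list alone, median −0.35, adjusted p = 0.0217, and adjusted p = 0.814 with an estimated correlation). The counts of these lists depend on the scaling: under median centring limma called 0 ribosomal proteins, 0 tubulins and 0 synthetases lower (6, 5 and 0 at an unadjusted p under 0.05), 7 cyclins and replication proteins, 1 proteasome subunit and 9 transposon-encoded proteins. Their medians stayed negative, at −0.02 for ribosomal proteins and −0.09 for tubulins. The count was 3775 of 19569 probes, 1430 up and 2345 down, with 430 and 238 at least 2-fold. It fell to 1702 under median centring, which also turned the share of calls that were higher from 37.9% to 68.1%. Without a filter it was 1981. Leaving out wild-type replicate 1 or 3 gave 2155 or 2196 and leaving out ppabi1a replicate 2 or 3 gave 2222 or 2126.

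In ppabi1b at 0 h the differences from wild type were smaller. The small heat-shock protein e_gw1.144.75.1 was higher by 3.48 ± 0.43 (adjusted p = 0.00219) and a glyceraldehyde 3-phosphate dehydrogenase, an enzyme of glycolysis (e_gw1.49.51.1), by 2.68 ± 0.34 (adjusted p = 0.00243). The myosin-related, Zn-finger and WASP-interacting genes were at least 3.16-fold, 2.11-fold and 1.65-fold higher. The other named rises were transposon-encoded, with at least 22.0-fold for fgenesh1_pg.scaffold_64000072, 3.24 ± 0.42 for fgenesh1_pg.scaffold_170000017 and 2.93 ± 0.23 for fgenesh1_pg.scaffold_636000002. Lower were a ferric reductase or NADPH oxidase relative (estExt_fgenesh1_pg.C_900003, −3.05 ± 0.77, adjusted p = 0.0259), an aquaporin (fgenesh1_kg.scaffold_1000012, −2.60 ± 0.54) and a calmodulin relative (e_gw1.107.250.1, −2.03 ± 0.44). The copper chaperone of superoxide dismutase (gw1.98.128.1, −2.57 ± 0.60) and a manganese superoxide dismutase, which removes superoxide (estExt_fgenesh1_pg.C_980074, −2.48 ± 0.63), were lower too.

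Transposon-encoded proteins stood out most in ppabi1b, with 14 of 26 higher and 0 lower (15 and 2 adjusted over the list alone, median 1.22, adjusted p = 2.59e-07, and adjusted p = 0.205 with an estimated correlation). All 14 were well above background on every ppabi1b array, enough to pass the filter (26 of 312 kept). But 11 were not on every array of the 4 genotypes and 6 were on no ppabi1a/b array. Tubulins were lower for 6 of 19 (8 adjusted over the list alone, median −0.21, adjusted p = 0.00509, and adjusted p = 0.73 with an estimated correlation), and for 1 under median centring. The count was 3336 of 19574 probes, 1533 up and 1803 down, with 221 and 206 at least 2-fold. It was 1309 under median centring, with 57.3% of calls higher, and 1255 without a filter. Without wild-type replicate 1 or 3 it was 1386 or 1503, and without ppabi1b replicate 1 or 3 it was 1692 or 1609.

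Set directly against ppabi1b, ppabi1a was higher for 367 of 554 genes that rose with 1 µM ABA and lower for 1 (median 1.10, adjusted over 14 tests p = 1.95e-89, and adjusted p = 0.0671 with an estimated correlation). The fasciclin-related gene was at least 308-fold higher, the endoplasmic reticulum membrane protein at least 15.8-fold. The reductase e_gw1.6.137.1 was higher by 6.35 ± 0.51, the Zn-finger gene by 6.12 ± 0.39 and the phospholipase C by 5.82 ± 0.71. Transposon-encoded proteins were lower in ppabi1a than in ppabi1b for 13 of 26 and higher for 1 (17 and 2 adjusted over the list alone, median −2.31, adjusted p = 6.57e-10, and adjusted p = 0.089 with an estimated correlation). Small shifts toward lower values in ppabi1a were called for aminoacyl-tRNA synthetases (6 of 47 lower, 6 adjusted over the list alone, median −0.17, adjusted p = 5.65e-06) and ribosomal proteins (4 of 394 lower, 1 higher, limma count 0 adjusted over the list alone and 63 lower at an unadjusted p under 0.05, median −0.08, adjusted p = 0.000123). They were also called for respiratory chain subunits (1 of 47 lower, 1 higher, 1 and 1 adjusted over the list alone, median −0.12, adjusted p = 0.0125), proteasome subunits (3 of 81 lower, 1 higher, 3 and 1 adjusted over the list alone, median −0.08, adjusted p = 0.031) and histones (5 of 61 lower, 5 adjusted over the list alone, median −0.10, adjusted p = 0.031). Histidine kinases shifted toward higher values (4 of 51 higher, 4 adjusted over the list alone, median 0.09, adjusted p = 0.00958). Under median centring limma called 0 ribosomal proteins and 0 synthetases lower (5 and 1 at an unadjusted p under 0.05), 2 histones lower and 2 histidine kinases higher. None of these 6 lists was called with an estimated correlation (adjusted p = 0.68 with an estimated correlation at the lowest). In all 1668 of 19580 probes differed, 971 higher and 697 lower in ppabi1a, with 388 and 135 at least 2-fold. Median centring gave 830 with 77.0% in place of 58.2% higher, the fit without a filter 715 and the fit of these 2 groups alone 1051. Leaving out ppabi1a replicate 1 or 2 or ppabi1b replicate 1 or 3 gave 1051, 903, 895 and 887.

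**Figure D3:**
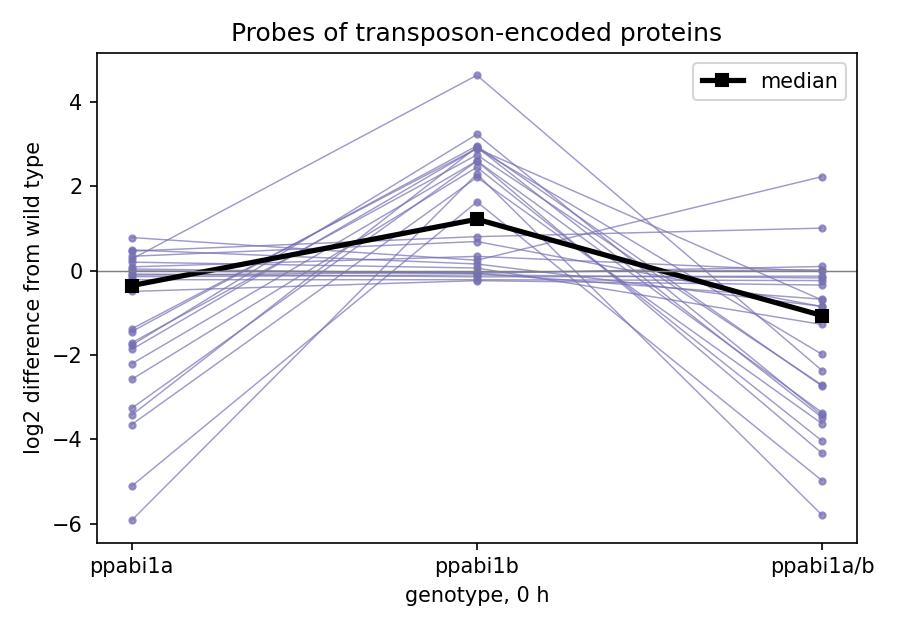
Log2 difference from wild type at 0 h of the 26 tested probes of transposon-encoded proteins in the 3 disruptants, 1 line per probe and the median in black. The median is −0.35 in ppabi1a, 1.22 in ppabi1b and −1.06 in ppabi1a/b.

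In ppabi1a/b at 0 h, without added ABA, the fasciclin-related gene was at least 6410.0-fold higher than in wild type, the Zn-finger gene at least 3622-fold and the myosin-related gene at least 1471-fold. The sorbitol dehydrogenase was at least 646-fold higher, an aldo/keto reductase (estExt_gwp_gw1.C_1410075) at least 601-fold and the WASP-interacting gene at least 253-fold. A poly(ADP-ribose) polymerase relative (fgenesh1_pg.scaffold_59000173) was at least 241-fold higher and the endoplasmic reticulum membrane protein at least 137-fold. These 8 were not well above background in wild type. The reductase e_gw1.6.137.1 was higher by 10.97 ± 0.51 and a transketolase (estExt_Genewise1.C_2130085), an enzyme of the pentose phosphate and Calvin cycles, by 9.38 ± 1.07 (adjusted p = 5.92e-05), each well above background on only 1 of 3 wild-type arrays. Lower were 2 DnaJ co-chaperones (e_gw1.54.265.1, −5.46 ± 0.57; gw1.18.87.1, −3.87 ± 0.37), a starch-binding protein (e_gw1.70.77.1, −4.51 ± 0.31, adjusted p = 2.1e-06) and the ferric reductase relative (adjusted p = 0.00163). Of these e_gw1.54.265.1, e_gw1.70.77.1 and the ferric reductase relative stood lower by 4.76, 5.99 and 4.91 in untreated wild type of the first set also.

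Of 66 antioxidant enzymes 22 were higher and 18 lower in ppabi1a/b (22 and 18 adjusted over the list alone, adjusted p = 0.197). A catalase (estExt_gwp_gw1.C_2920023) was higher by 8.63 ± 0.28 and a glutaredoxin (gw1.42.246.1) by 3.67 ± 0.19. Small heat-shock proteins were called higher as a list (10 of 19 higher, 3 lower; 11 and 4 adjusted over the list alone, median 0.57, adjusted p = 0.0231, and adjusted p = 0.962 with an estimated correlation). Members e_gw1.144.75.1 and fgenesh1_pg.scaffold_38000175 were higher by 8.69 ± 0.43 and 2.09 ± 0.14. The phosphatases of KOG0698 were called lower (24 of 36 lower, 3 higher; 25 and 3 adjusted over the list alone, median −0.45, adjusted p = 0.0062, and adjusted p = 0.588 with an estimated correlation). The list includes both lost models, while estExt_fgenesh1_pg.C_930093 was higher by 4.12 ± 0.19. Transposon-encoded proteins were lower for 17 of 26 and higher for 2 (18 and 2 adjusted over the list alone, median −1.06, adjusted p = 0.0062, and adjusted p = 0.588 with an estimated correlation). Of 19 phenylpropanoid enzymes 15 were lower and 2 higher (16 and 2 adjusted over the list alone, median −1.77, adjusted p = 0.0537, but 0.0486 with the replicate block and 0.0245 under quantile normalization, and not called with an estimated correlation). Calcium-dependent protein kinases were lower for 16 of 30 and higher for 3 (18 and 3 adjusted over the list alone, median −0.34, adjusted p = 0.27), with −2.27 ± 0.19 for fgenesh1_pg.scaffold_199000038. Among trehalose-6-phosphate synthases and invertases 9 of 16 were lower and 2 higher (9 and 2 adjusted over the list alone), with −2.24 ± 0.13 for the invertase that fell with 1 µM ABA.

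The count was 10541 of 19575 probes, 3842 up and 6699 down, with 1186 and 1840 at least 2-fold. Direction depends on the scaling, since median centring moved the median of all genes from −0.11 to 0.13. It gave 1619 higher and 1120 lower at least 2-fold, with 64.0% in place of 36.4% of all calls higher.

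The double disruptant departed from the sum of both single disruptants for 6440 of 19558 probes, 2776 above and 3664 below that sum, with 965 and 1522 at least 2-fold. Above it were 2 aquaporins (e_gw1.118.8.1, 7.91 ± 0.69, adjusted p = 5.21e-05; fgenesh1_pg.scaffold_17000160, 6.63 ± 1.47) and the transketolase (7.06 ± 1.52, and 5.31 with ppabi1b, where it was not well above background, set to the lowest level well above it). Several genes below background in wild type and in both single disruptants stood above the sum even with each dim group set to the lowest level well above background. The poly(ADP-ribose) polymerase relative did so by 8.36, a maltase relative (estExt_Genewise1.C_130346) by 6.74, a citrate synthase, which opens the citric acid cycle (fgenesh1_pg.scaffold_56000124), by 6.55 and a guanylate-binding protein (e_gw1.391.4.1) by 6.21. Below the sum were 2 proteins with an SCP domain (estExt_Genewise1.C_330102, −4.15 ± 0.34; fgenesh1_pg.scaffold_33000079, −4.13 ± 0.35) and a phosphoglycerate kinase, an enzyme of glycolysis (estExt_fgenesh1_pg.C_1180019, −3.34 ± 0.80, adjusted p = 0.0107). Lists above the sum were ribosomal proteins (28 of 392 above, 7 below; 18 and 4 adjusted over the list alone, median 0.07, adjusted p = 0.00465) and cyclins and replication proteins (24 of 81 above, 4 below; 24 and 4 adjusted over the list alone, adjusted p = 0.0153). Respiratory chain subunits (7 of 47 above; 5 adjusted over the list alone, adjusted p = 0.0239) and tubulins (8 of 19 above, 1 below; 8 and 1 adjusted over the list alone, adjusted p = 0.0376) stood above it as well. Below were transposon-encoded proteins (15 of 26 below, 1 above; 16 and 2 adjusted over the list alone, median −1.72, adjusted p = 0.000507) and the phosphatases of KOG0698 (13 of 36 below, 2 above; 13 and 3 adjusted over the list alone, adjusted p = 0.0453). With an estimated correlation none of the 6 was called (adjusted p = 0.698 with an estimated correlation for ribosomal proteins, 0.681 for the others). Median centring moved the median of all genes from −0.03 to 0.09.

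How far the disruptants at 0 h share the early ABA response was asked with the genes that changed with 1 µM ABA in the first experiment, with other arrays and controls. The 563 genes that rose had a median of 1.21 in ppabi1a, where 404 of 554 tested were higher and 1 lower. It was 0.18 in ppabi1b (98 of 555 higher, 16 lower) and 2.35 in ppabi1a/b (497 of 555 higher, 9 lower). With genes below background in a group at their bound, the medians were 1.13, 0.17 and 2.13. Over the 862 rises with the replicate block they were lower in ppabi1a and ppabi1a/b (last section). With camera, over a family of 6 tests, the list was called higher in ppabi1a (adjusted p = 9.25e-79), ppabi1b (adjusted p = 4.53e-06) and ppabi1a/b (adjusted p = 8.43e-66). With an estimated correlation (0.43, preset 0.01) none of these calls was kept (adjusted p = 0.0616 in ppabi1a and ppabi1a/b and 0.458 in ppabi1b). With fry the list was called in ppabi1a (adjusted p = 4.09e-05) and ppabi1a/b (adjusted p = 1.64e-06) and not in ppabi1b (adjusted p = 0.254). The 78 genes that fell had medians of −0.37, −0.18 and −0.63, with 29, 18 and 46 of 75 lower. These were called (adjusted p = 2.22e-06, 0.00107 and 1.82e-05, and adjusted p = 0.308, 0.394 and 0.308 with an estimated correlation). Above the sum of the single disruptants, the genes that rose lay by a median of 0.50 in ppabi1a/b (199 of 553 above, 27 below, adjusted p = 2.33e-11, and adjusted p = 0.454 with an estimated correlation).

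Across genes, which are not independent replicates, the 1 µM response correlated with the ppabi1a difference by r = 0.72 (rho 0.41, 18662 genes). It correlated with that of ppabi1b by r = 0.27 (rho 0.16) and with that of ppabi1a/b by r = 0.72 (rho 0.40). Of genes that rose at least 2-fold with 1 µM ABA, 293 were also at least 2-fold higher in ppabi1a against 12.3 expected by chance, 56 in ppabi1b against 5.89 and 418 in ppabi1a/b against 29.0.

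**Figure D4:**
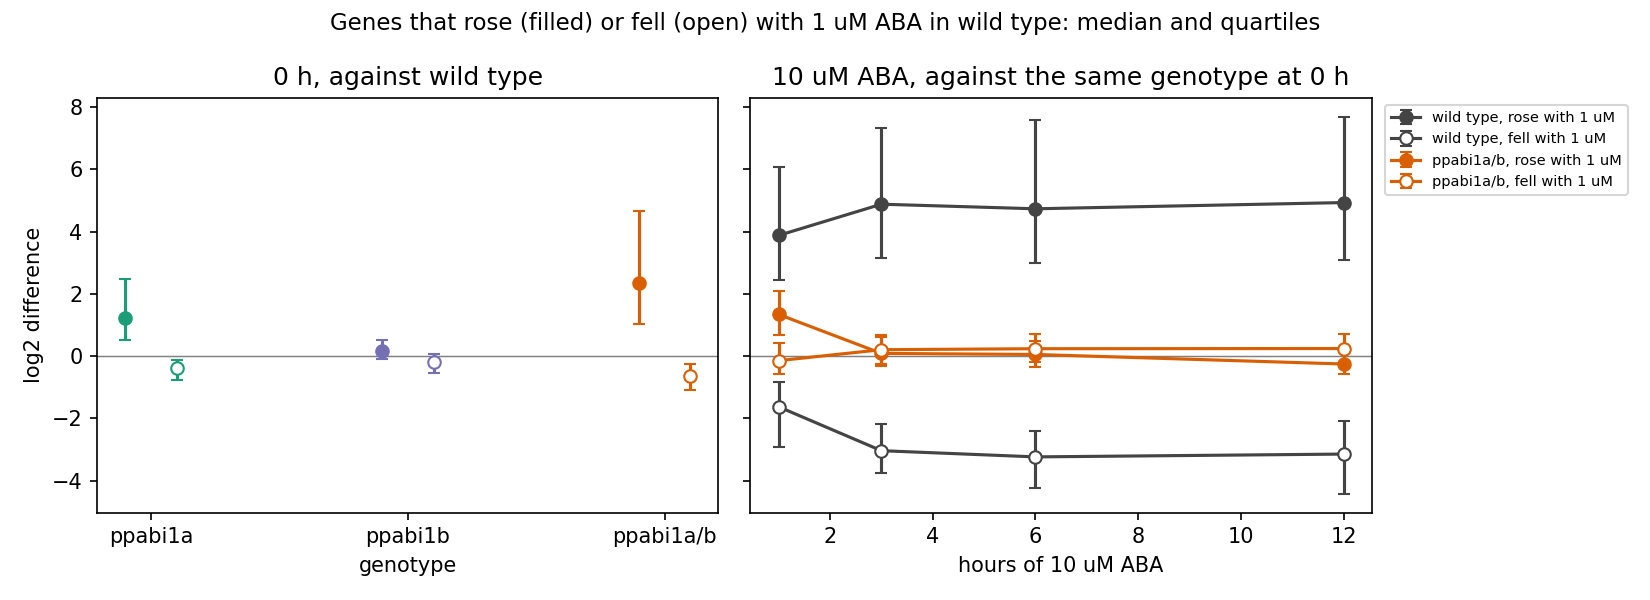
Median and quartiles of the log2 difference of genes that rose (filled) or fell (open) at least 2-fold with 1 µM ABA, in the disruptants against wild type at 0 h (left) and at each hour of 10 µM ABA against 0 h of the same genotype (right, 1 array per time). At 0 h the medians of the genes that rose are 1.21, 0.18 and 2.35, and at 3 h of 10 µM ABA they are 4.88 in wild type and 0.09 in ppabi1a/b.

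In wild type, 10 µM ABA raised the Zn-finger gene at least 12655.5-fold over 0 h, the fasciclin-related gene at least 8764-fold and the sorbitol dehydrogenase at least 3034-fold, as means over 1 to 12 h. The aldo/keto reductase rose at least 2661-fold, the myosin-related gene at least 2586-fold and the phospholipase C at least 2304-fold. The WASP-interacting gene rose at least 1330.2-fold and the endoplasmic reticulum membrane protein at least 1056-fold. The reductase e_gw1.6.137.1 rose by 12.23 ± 1.38, the transketolase by 12.00 ± 1.08 and the catalase estExt_gwp_gw1.C_2920023 by 11.58 ± 0.63 (adjusted p = 9.39e-08). These sizes rest on signal near background, since at 0 h the genes were well above it on only 1, 1 and 2 of 3 arrays. The largest falls were a lipase (estExt_Genewise1.C_390260, −7.62 ± 0.97), a mitochondrial oxoglutarate/malate carrier (estExt_fgenesh1_pg.C_2320004, −7.32 ± 0.53) and an NDR1-related protein (estExt_Genewise1.C_3350030, −7.30 ± 0.20, adjusted p = 1.08e-09). They were followed by a calmodulin relative (e_gw1.4.159.1, −7.12 ± 1.09) and a phenylalanine ammonia-lyase, the entry enzyme of phenylpropanoid synthesis (estExt_gwp_gw1.C_320152, −6.94 ± 0.87, adjusted p = 4.57e-05). Under ABA the first 4 of these were well above background on only 1, 2, 1 and 1 of 4 arrays, so their sizes too rest on signal near it. The carrier, the NDR1-related protein and e_gw1.4.159.1 stood lower by 6.11, 4.45 and 4.46 in untreated wild type of the first set also. At 1, 3, 6 and 12 h, the catalase stood 9.58, 12.14, 12.19 and 12.41 above 0 h and the reductase 7.28, 12.73, 14.33 and 14.57. The ammonia-lyase stood at −4.86, −8.08, −6.20 and −8.60.

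Receptor-like kinases fell as a list in wild type (149 of 271 fell, 31 rose, 153 and 31 adjusted over the list alone, median −0.78, adjusted p = 4.88e-05, and adjusted p = 0.179 with an estimated correlation). Kinase estExt_Genewise1.C_1340071 fell by 2.97 ± 0.13. Calcium-dependent protein kinases fell (17 of 30 fell, 3 rose; 17 and 3 adjusted over the list alone, median −0.45, adjusted p = 0.0102, and adjusted p = 0.179 with an estimated correlation). Among these fgenesh1_pg.scaffold_199000038 stood at −4.62 ± 0.27. Phenylpropanoid enzymes fell (15 of 19 fell, 2 rose; 16 and 2 adjusted over the list alone, median −2.19, adjusted p = 0.0117, and adjusted p = 0.721 with an estimated correlation). A cinnamoyl-CoA reductase relative (fgenesh2_pg.scaffold_76000011) rose by 4.30 ± 0.38. The lists that fell were lower in the untreated first set too. Small heat-shock proteins rose (15 of 19 rose, 2 fell; 16 and 2 adjusted over the list alone, median 0.98, adjusted p = 0.0102, and adjusted p = 0.385 with an estimated correlation). Examples are e_gw1.11.155.1 (5.17 ± 0.56) and fgenesh1_pg.scaffold_38000175 (4.52 ± 0.59). Proteasome subunits rose by a small amount (37 of 80 rose, 6 fell, 37 and 6 adjusted over the list alone, median 0.25, adjusted p = 0.0102, and adjusted p = 0.385 with an estimated correlation), with 1.06 ± 0.12 for estExt_gwp_gw1.C_540015. Under quantile normalization this list was not called (19 rose, 8 fell, median 0.05, adjusted p = 0.295).

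The other 29 lists were not called against the remaining genes in wild type, but many members changed, and under quantile normalization 1 of them, ribosomal proteins, was called lower (adjusted p = 2.6e-08). Below, the second pair of counts for a list is that adjusted over the list alone. Of 66 antioxidant enzymes 26 rose and 16 fell (26 and 17, adjusted p = 0.109), with 6.41 ± 0.41 for the catalase e_gw1.3.315.1 and 5.73 ± 0.33 for the glutaredoxin gw1.42.246.1. Of 36 phosphatases of KOG0698, 7 rose and 15 fell (7 and 15 adjusted over the list alone, adjusted p = 0.298), with 6.42 ± 0.41 for estExt_fgenesh1_pg.C_930093, and of 9 of KOG0700, 0 rose and 5 fell (0 and 5 adjusted over the list alone, adjusted p = 0.162). Of 22 Myb factors, 3 rose and 13 fell (3 and 13, adjusted p = 0.114). Of 9 MADS box factors, 1 rose and 4 fell (1 and 4, adjusted p = 0.109), with −3.78 ± 0.30 for e_gw1.55.5.1. Of 18 bZIP factors, 4 rose and 4 fell (4 and 4, adjusted p = 0.843), with 2.93 ± 0.34 for estExt_fgenesh1_pg.C_220219. Of 37 members of the MAP kinase cascade, 3 rose and 11 fell (3 and 11, adjusted p = 0.428). Of 51 histidine kinases, 16 rose and 13 fell (16 and 13, adjusted p = 0.696). Of 18 aquaporins, 4 rose and 8 fell (4 and 8, adjusted p = 0.638), with 5.03 ± 0.45 for estExt_gwp_gw1.C_370175. Of 80 ABC transporters, 26 rose and 30 fell (27 and 32, adjusted p = 0.926). Of 19 amino acid transporters, 4 rose and 7 fell (4 and 7, adjusted p = 0.926, median −0.28, mean 0.13, test down). Of 55 genes of potassium transport, 15 rose and 18 fell (15 and 18, adjusted p = 0.975, median −0.13, mean −0.06, test up).

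Of 74 lipases and phospholipases, 31 rose and 30 fell (32 and 31, adjusted p = 0.666, median −0.09, mean 0.26, test up), with 5.38 ± 0.42 for the phospholipase D e_gw1.19.181.1. Of 20 starch enzymes, 3 rose and 10 fell (3 and 10, adjusted p = 0.428). Of 16 trehalose-6-phosphate synthases and invertases, 4 rose and 6 fell (4 and 6, adjusted p = 0.564), with −3.87 ± 0.32 for the invertase estExt_fgenesh1_pm.C_660005. Of 9 enzymes of chlorophyll and haem synthesis, 1 rose and 6 fell (1 and 7, adjusted p = 0.407). Of 60 cytochromes P450, 12 rose and 22 fell (12 and 22, adjusted p = 0.407). Of 16 aldehyde dehydrogenases, 5 rose and 5 fell (5 and 5, adjusted p = 0.575). Of 47 respiratory chain subunits, 8 rose and 13 fell (7 and 12, adjusted p = 0.564, median −0.13, mean 0.07, test down). Of 80 cyclins and replication proteins, 9 rose and 32 fell (9 and 32, adjusted p = 0.356), with −2.40 ± 0.22 for a cyclin D (estExt_Genewise1.C_3590009). Of 61 histones, 13 rose and 22 fell (13 and 23, adjusted p = 0.537). Of 20 tubulins, 2 rose and 9 fell (2 and 9, adjusted p = 0.356). Of 40 kinesins, 8 rose and 16 fell (9 and 18, adjusted p = 0.739). Of 47 aminoacyl-tRNA synthetases, 8 rose and 12 fell (7 and 11, adjusted p = 0.926). Of 149 splicing factors, 44 rose and 28 fell (44 and 28, adjusted p = 0.363). Ribosomal proteins (56 of 393 rose, 56 fell; 23 and 34, adjusted p = 0.638, median 0.03, mean −0.01, test up), chaperones (73 of 251 rose, 64 fell; 72 and 64, adjusted p = 0.564, median 0.02) and E3 ubiquitin ligases (61 of 203 rose, 64 fell; 61 and 64, adjusted p = 0.992, median 0.04, mean −0.12, test up) had medians that turned to −0.37, −0.12 and −0.04 under quantile normalization. Of 22 transposon-encoded proteins 5 rose and 3 fell (5 and 3, adjusted p = 0.252).

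In all 10996 of 19499 probes changed in wild type, 4997 up and 5999 down, with 2275 and 3368 at least 2-fold. Of the genes that rose with 1 µM ABA 551 of 559 rose with 10 µM and 1 fell (median 4.65, and 4.54 with dim genes at their bound, adjusted p = 1.65e-64, and adjusted p = 0.0685 with an estimated correlation). Of those that fell, 76 of 77 fell (median −2.88, adjusted p = 1.94e-19, and adjusted p = 0.0685 with an estimated correlation). At 3 h the median over 547 of the former was 3.06 at 1 µM and 4.88 at 10 µM, with 532 higher at 10 µM, doses that were given in different experiments. Single wild-type arrays stood at least 2-fold from the 0 h mean for 2208 probes up and 2897 down at 1 h and for 3409 and 4082 at 12 h. Each 0 h array stood so far from the mean of the other 2 for 83 to 443 up and 135 to 208 down.

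In ppabi1a/b under 10 µM ABA, set against its own 0 h arrays, 133 of the 422 genes that rose at least 2-fold did so in wild type too (49.2 expected by chance) and 67 fell there. Of the 437 that fell and were tested in both, 287 fell in wild type too (75.5 expected) and 22 rose. Rises included a sodium/dicarboxylate transporter (estExt_fgenesh1_pg.C_880112, at least 25.0-fold), a sodium/phosphate symporter (fgenesh1_pg.scaffold_4000236, at least 17.2-fold) and 2 calmodulin relatives (fgenesh1_pg.scaffold_1000466, 3.98 ± 0.78, and gw1.88.98.1, 3.92 ± 0.59). A GATA factor (fgenesh1_pg.scaffold_22000036, 3.93 ± 0.53, which was −3.71 between the untreated sets) and a fatty acid elongase (estExt_gwp_gw1.C_2510019, 3.35 ± 0.48, adjusted p = 0.0015) rose as well. Falls included an ABC transporter (e_gw1.65.47.1, −3.21 ± 0.55), a Zn-finger protein (gw1.37.119.1, −2.64 ± 0.15, adjusted p = 5.07e-06), the small GTPase Arf1 (estExt_Genewise1.C_280076, −2.41 ± 0.12, adjusted p = 3.43e-06) and an E3 ubiquitin ligase (gw1.56.138.1, −2.27 ± 0.34). Of the genes that rose with 1 µM ABA, 15 of 559 rose and 5 fell in ppabi1a/b (median 0.30, adjusted p = 0.0542 over 14 tests). Their medians at 1, 3, 6 and 12 h were 1.34, 0.09, 0.05 and −0.25 against 3.88, 4.88, 4.74 and 4.93 in wild type. The catalase stood at 3.07, 1.72, 1.58 and 1.04 above its own 0 h level.

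Chaperones rose in ppabi1a/b (56 of 250 rose, 12 fell; 73 and 15 adjusted over the list alone, median 0.23, and 0.02 under median centring, adjusted p = 0.00103, and adjusted p = 0.319 with an estimated correlation). So did aminoacyl-tRNA synthetases (7 of 47 rose; 7 adjusted over the list alone, median 0.21, which turned to −0.01 under median centring, adjusted p = 0.00107, and adjusted p = 0.609 with an estimated correlation) and small heat-shock proteins (4 of 19 rose; 4 adjusted over the list alone, median 0.63, adjusted p = 0.0484, and adjusted p = 0.563 with an estimated correlation). MADS box factors (4 of 9 fell; 5 adjusted over the list alone, median −0.54, adjusted p = 0.00103), phosphatases of KOG0700 (3 of 9 fell; 5 adjusted over the list alone, median −0.37, adjusted p = 0.00359) and the MAP kinase cascade (6 of 37 fell, 1 rose; 7 and 1 adjusted over the list alone, median −0.17, adjusted p = 0.0108) fell, each with adjusted p = 0.0596 with an estimated correlation. Ribosomal proteins (62 of 393 fell, 5 rose; 69 and 7 adjusted over the list alone, median −0.07, adjusted p = 0.000111), E3 ubiquitin ligases (36 of 203 fell, 7 rose; 40 and 9 adjusted over the list alone, median −0.05, adjusted p = 0.00359) and receptor-like kinases (40 of 272 fell, 11 rose; 47 and 11 adjusted over the list alone, median −0.09, adjusted p = 0.0314) fell too, with adjusted p = 0.609, 0.294 and 0.392 with an estimated correlation.

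The count in ppabi1a/b was 2887 of 19508 probes, 1346 up and 1541 down, with 422 and 439 at least 2-fold. It was 7164, 1497 and 1703 without the 1 h, 3 h or 6 h array and 1238, 1745 and 1203 without replicate 1, 2 or 3 at 0 h. It was 1374 without a filter, 7167 with the slide as a random block and 7337 with 6 h and 12 h alone. Median centring moved the median of all genes from 0.05 to −0.17 and the share of calls that rose from 46.6% to 13.7%.

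The test of whether both genotypes respond alike called 7403 of 19478 probes, with a response higher in ppabi1a/b for 4164 and lower for 3239, of which 2873 and 1873 at least 2-fold. The response of ppabi1a/b less that of wild type was −13.09 for the Zn-finger gene, −12.92 for the fasciclin-related gene, −10.74 for the myosin-related gene, −10.59 for the sorbitol dehydrogenase and −9.20 for the phospholipase C, with untreated wild type set to the lowest level well above background. The reductase e_gw1.6.137.1 differed by −11.25 ± 1.95, the transketolase by −10.79 ± 1.53 and the gene related to meiotic chromosome segregation (e_gw1.2.84.1) by −10.08 ± 0.64 (adjusted p = 1.74e-06). As these were well above background on only 1, 1 and 2 of the 3 untreated wild-type arrays, the sizes are fitted values that rest on signal near background. Toward a higher response in ppabi1a/b stood 2 GDP-mannose pyrophosphorylases, which make a precursor of cell wall sugars and ascorbate (e_gw1.98.38.1, 7.76 ± 0.92, adjusted p = 0.000105; fgenesh1_pg.scaffold_2000106, 6.77 ± 0.82). With them stood an ammonia permease (e_gw1.4.342.1, 6.78 ± 1.94), the lipase estExt_Genewise1.C_390260 (6.73 ± 1.37) and a cyclin-dependent kinase inhibitor (estExt_fgenesh1_pg.C_4950001, 6.21 ± 1.14, n = 3 arrays with a value in treated ppabi1a/b). In treated wild type fgenesh1_pg.scaffold_2000106, the permease and the lipase were well above background on only 1, 2 and 1 of 4 arrays. The first of the pyrophosphorylases stood at −3.26, −5.81, −6.43 and −6.71 in wild type at 1, 3, 6 and 12 h and at 1.63, 2.29, 2.52 and 2.39 in ppabi1a/b.

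Of the genes that rose with 1 µM ABA 531 of 558 had a lower response in ppabi1a/b (median −4.37, and −4.18 with dim genes at their bound, adjusted p = 7.9e-72, and adjusted p = 0.0685 with an estimated correlation). Of those that fell, 70 of 77 had a higher one (median 2.72, and 2.52 at their bound, adjusted p = 4.44e-20, and adjusted p = 0.0685 with an estimated correlation). Receptor-like kinases, high in the second untreated set, had a higher response (109 of 271, 31 lower, 114 and 33 adjusted over the list alone, median 0.72, adjusted p = 0.00739, and adjusted p = 0.69 with an estimated correlation). Ribosomal proteins had a lower one (17 of 392 higher, 53 lower; 5 and 16 adjusted over the list alone, adjusted p = 0.00739, and adjusted p = 0.71 with an estimated correlation), with a median of −0.14 that turned to 0.23 under quantile normalization, where the list was called in the other direction (adjusted p = 0.028). The count was 11318 without the 1 h arrays and 11889 with 6 h and 12 h alone. Median centring moved the median of all genes from 0.08 to −0.12 and the share of higher responses from 56.2% to 41.8%. Treated arrays of a genotype lay on 1 slide and 0 h arrays on 3 others, so slide cannot be told apart from genotype under treatment, nor from treatment in either. In wild type 551 of 559 rises and 76 of 77 falls at 1 µM, on shared slides, recurred. This argues against slide for these genes there.

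Under 10 µM ABA itself, paired by time, ppabi1a/b differed from wild type for 5609 of 19114 probes, 2809 higher and 2800 lower, with 1808 and 1485 at least 2-fold. Lower in ppabi1a/b were 2 enzymes of the glyoxylate cycle, malate synthase (e_gw1.40.43.1, −5.41 ± 0.55, adjusted p = 0.00814) and isocitrate lyase (estExt_gwp_gw1.C_1360145, −4.80 ± 0.58, adjusted p = 0.0111), and a splicing coactivator relative (estExt_fgenesh1_pg.C_1610006, −5.15 ± 0.32). At 1, 3, 6 and 12 h isocitrate lyase stood 1.57, 2.83, 5.08 and 4.45 above 0 h in wild type and 0.43, 0.21, 0.47 and 1.33 in ppabi1a/b. Higher in ppabi1a/b were the ammonia permease (7.11 ± 1.63, adjusted p = 0.0374), a copper chaperone (e_gw1.328.32.1, at least 29.7-fold), the aquaporin e_gw1.118.8.1 (at least 27.5-fold), a chitinase (estExt_fgenesh1_pg.C_3000004, 5.97 ± 0.86) and a cytochrome P450 (estExt_gwp_gw1.C_690054, 5.92 ± 0.97). The permease and the P450 were well above background on only 2 and 1 of 4 treated wild-type arrays. Of the genes that rose with 1 µM ABA 313 of 558 were lower in ppabi1a/b (median −1.85, adjusted p = 3.1e-27, and adjusted p = 0.454 with an estimated correlation).

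Receptor-like kinases were higher under ABA in ppabi1a/b (74 of 264 higher, 28 lower; 90 and 40 adjusted over the list alone, median 0.46, adjusted p = 0.00668). So were cyclins and replication proteins (13 of 80 higher, 3 lower; 12 and 3 adjusted over the list alone, median 0.32, adjusted p = 0.0136). Proteasome subunits (14 of 82 lower, 2 higher, median −0.26, adjusted p = 0.00752) and ribosomal proteins (33 of 394 lower, 8 higher, median −0.23, which turned to 0.12 under quantile normalization, adjusted p = 0.000808) were lower, although the limma counts adjusted over the list alone were 0 (29 and 126 lower at an unadjusted p under 0.05). Transposon-encoded proteins were lower too (10 of 22 lower, 1 higher; 10 and 1 adjusted over the list alone, median −1.06, adjusted p = 0.00752). With an estimated correlation the kinases had adjusted p = 0.63 and the other 4 lists adjusted p = 0.82. Under quantile normalization only transposon-encoded proteins stayed called (adjusted p = 0.0185), and the kinases (adjusted p = 0.0579), cyclins and replication proteins, ribosomal proteins (adjusted p = 0.121 each) and proteasome subunits (adjusted p = 0.223) were not. The count rests on single times. It was 10606, 465, 38 and 1261 without the 1 h, 3 h, 6 h or 12 h pair, 9064 with 6 h and 12 h alone and 2744 without a filter. Of the 24 genes named by size, 18 lost the threshold without the 6 h pair and 8 each without 3 h or 12 h. With normexp correction 36.2% in place of 50.1% of calls were higher.

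Both untreated wild-type sets differed, though on both components replicate 1 of the first lay nearest the second set. In the second set the mitochondrial carrier estExt_fgenesh1_pg.C_2320004 was higher by 6.11 ± 1.29 (adjusted p = 0.0389), a TRAF-related protein (e_gw1.37.21.1) by 6.08 ± 0.95, the starch-binding protein e_gw1.70.77.1 by 5.99 ± 0.95 and a DnaJ co-chaperone (e_gw1.54.265.1) by 4.76 ± 0.83. Lower there were 2 GATA factors (fgenesh1_pg.scaffold_22000036, −3.71 ± 0.55; fgenesh1_pg.scaffold_2000003, −3.15 ± 0.32), an oligopeptide symporter (e_gw1.114.185.1, −2.91 ± 0.39) and an RNA helicase (gw1.13.52.1, −2.73 ± 0.20). Lists higher in the second set were receptor-like kinases (40 of 245 higher, 6 lower; 70 and 10 adjusted over the list alone, median 0.43, adjusted p = 3.06e-07) and lipases (13 of 70, 1 lower; 19 and 1 adjusted over the list alone, adjusted p = 9.91e-05). E3 ubiquitin ligases (24 of 198, 4 lower; 37 and 6 adjusted over the list alone, adjusted p = 0.000431) and histidine kinases (3 of 49; 3 adjusted over the list alone, adjusted p = 0.00637) were higher. So were aquaporins (2 of 15; 2 adjusted over the list alone, adjusted p = 0.0143), calcium-dependent protein kinases (4 of 29; 7 adjusted over the list alone, adjusted p = 0.0199). Cytochromes P450 (5 of 55; 7 and 1 adjusted over the list alone, adjusted p = 0.0261) and phosphatases of KOG0698 (5 of 36; 6 and 1 adjusted over the list alone, adjusted p = 0.0465) were higher too. Phenylpropanoid enzymes had a median of 1.96 (adjusted p = 0.0164) with 0 of 19 called by limma over all genes or over the list alone, and 11 higher and 1 lower at an unadjusted p under 0.05. Aminoacyl-tRNA synthetases were lower (4 of 47, 1 higher; 8 and 1 adjusted over the list alone, median −0.45, adjusted p = 0.000425). None of these 10 lists was called with an estimated correlation, the lowest being lipases with adjusted p = 0.141 with an estimated correlation.

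In all 2336 of 19045 probes differed between the sets, 1129 higher and 1207 lower in the second, with 735 and 537 at least 2-fold. The count was 10651, 1410 and 254 without replicate 1, 2 or 3 of the first set. It was 0, 1 and 0 without replicate 1, 2 or 3 of the second, where limma found 4362, 4838 and 4311 probes at an unadjusted p under 0.05 and all 24 genes named by size lost the threshold. It was 1122 with normexp correction, with 58.7% in place of 48.3% of calls higher, and 0 without a filter (limma, 6232 at an unadjusted p under 0.05). Median centring moved the median of all genes from −0.08 to −0.22 and gave 33.7% of calls higher.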

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

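Chosen after their results were seen were the comparison of ppabi1a with ppabi1b, the fit of 6 h and 12 h alone, and the tests for the slide of the treated arrays, for the scan day and for the wild-type ABA response in ppabi1a/b.

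In 5 cases the value of a single array lay far from those of the other 3 arrays of the same genotype under 10 µM ABA. With 86 groups tested chance gives about 1 in 20, here 4.30, so 5 are close to the number chance gives. In wild type at 1 h the genes that fell with 1 µM ABA had a median of −1.63 against −3.24 to −3.04 at the other times, and amino acid transporters −0.28 against −0.25 to −0.24. In ppabi1a/b at 1 h the genes that fell with 1 µM ABA stood at −0.14 against 0.21 to 0.24 later, at 12 h aquaporins stood at −0.47 against −0.08 to −0.03, and 140 spots were marked as outliers at 12 h against 125 to 127 on the other arrays. Each time had 1 array, so time and array cannot be separated here.

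A difference between groups was found by a direct test in 6 results: the response to 10 µM ABA differed between wild type and ppabi1a/b for 7403 genes, with a median of −4.37 over the genes that rose with 1 µM ABA, of 0.72 over receptor-like kinases and of −0.14 over ribosomal proteins (0.23 under quantile normalization), and ppabi1a differed from ppabi1b at 0 h for 1668 genes, with a median of 1.10 over the genes that rose with 1 µM ABA. None of the 4 list results was called with an estimated correlation: the genes that rose with 1 µM ABA had adjusted p = 0.0685 with an estimated correlation for the response and 0.0671 between the single disruptants, receptor-like kinases 0.69 and ribosomal proteins 0.71.

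The smaller response of these genes to 10 µM ABA in ppabi1a/b was weighed first. Were it due only to levels already raised at 0 h, genes at the wild-type level would respond alike, but 65 genes within 0.5 of wild type at 0 h had a median difference in response of −2.05 (quartiles −2.37 to −1.63), rising by a median of 2.26 in wild type and 0.11 in ppabi1a/b, which argues against this as the whole cause. Scaling between arrays is argued against by a median of −4.32 for all these genes under quantile normalization and −4.57 under median centring, and the dimmer wild-type arrays at 1 h and 3 h by −4.98 with 6 h and 12 h alone. Treated arrays of both genotypes shared 0 slides with each other and with the 0 h arrays, so their slide cannot be told apart from the genotype, nor from the treatment in ppabi1a/b. Reduced ABA sensitivity in the disruptant may be the reason and stays a hypothesis beside that slide.

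The second pattern is that the ppabi1a/b change under 10 µM ABA ran along the difference between both untreated wild-type sets (first less second), with r = 0.545 across 16357 genes, which are not independent replicates, and no shared arrays. It was uneven: r of single arrays with the other comparison was 0.215, 0.536 and 0.566 for replicates 1, 2 and 3 of the first set and 0.318, 0.562, 0.509 and 0.513 for ppabi1a/b at 1, 3, 6 and 12 h. Of 367 genes that rose at least 2-fold in ppabi1a/b, 315 were higher in the first set (85.8%, against 54.6% of all genes), and of 419 that fell 399 were lower there (95.2%, against 45.4%). A signal-dependent bias is argued against by a lowest r of 0.537 in 3 equal signal classes, and the scan day by the ppabi1a/b arrays sharing 1 day. The wild-type ABA response stays open: r was 0.163 with the 1 µM change, which holds the first set with opposite sign. Wild type under 10 µM shared 133 of 422 rises and 287 of 437 falls (49.2 and 75.5 expected). The state or handling of the cultures may differ alike in both comparisons and stays open, since the series holds no mock-treated arrays.

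The third pattern is that transposon-encoded probes stood higher in ppabi1b and lower in ppabi1a and ppabi1a/b than in wild type. Probes shared between copies of an element stay open: 0 of 26 tested probes shared 20 bases or more with another, but other copies were not searched. Scaling between arrays is argued against by a median in ppabi1b of 1.25 in the weaker case, with −0.82 in ppabi1a/b. Signal close to background cannot be told apart: over the 12 members well above it on every array the median in ppabi1b was 0.0149, but the falls in ppabi1a and ppabi1a/b themselves decide which members are left out, 11 of the 14 that rose among them. All 14 met the filter by their ppabi1b arrays. Separate plant lines may also differ, which was not tested.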

How the results depend on the processing

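Chosen after the data were seen were the comparison of ppabi1a with ppabi1b and its alternatives, the 1 µM comparison without slide 1, the lists from that fit and from the fit with the replicate block, and the fits of 6 h and 12 h alone.

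Of the results that answer a comparison, 148 recomputed values stayed within 1.5 times or on the same side of the threshold, 51 counts moved further, 2 values lost their threshold and 0 reversed, which counts cannot. These values hold, for the genes that changed with 1 µM ABA, only those that rose and by unadjusted p, and for other lists only the number of calls. With adjustment, all 3 calls of the genes that rose were lost with an estimated correlation, as were those of the genes that fell even by unadjusted p (0.159, 0.328 and 0.206 in ppabi1a, ppabi1b and ppabi1a/b). Of 264 values of named genes, 3604 of 3977 recomputations kept direction and threshold (90.6%), 373 lost the threshold and 0 reversed. The losses were uneven: 18 to 22 of the 24 genes named for 1 µM ABA lost it without 1 treated array, 4, 9 and 20 without untreated replicate 1, 2 or 3, 13 without slide 1 and 0 with the replicate block, 18 of 24 between genotypes under ABA without the 6 h pair and 8 each without 3 h or 12 h, 7 of 24 for ppabi1b without wild-type replicate 1 or 3, and 24 of the 24 between the untreated sets without any 1 array of the second set (10 and 19 without replicate 2 or 3 of the first). Without a filter on dim probes, which tests more probes, counts were 304 for 1 µM ABA, 1981 for ppabi1a, 1255 for ppabi1b, 715 between these, 1374 for 10 µM in ppabi1a/b, 2744 between genotypes under ABA and 0 between the untreated sets (limma, 6232 at an unadjusted p under 0.05). Median centring gave 1702 for ppabi1a, 1309 for ppabi1b and 830 between them, normexp 1122 between the untreated sets, and the fit of 2 groups alone 1051 between the single disruptants, and for these the cause was not tested. The replicate number as a block gave 1691 for 1 µM ABA (63.2% up in place of 87.6%), and moved no other count by over 1.5 times (4401 for ppabi1a, 3853 for ppabi1b, 11016 for ppabi1a/b, 6910 against the sum, 1876 between the single disruptants). The slide as a random block gave 7167 for 10 µM in ppabi1a/b (correlation −0.306, no slide shared by 0 h and treated arrays), and a fixed replicate block in the 10 µM comparisons was not run, since it could not be estimated. Without the 1 h, 3 h and 6 h arrays the same count was 7164, 1497 and 1703, and 7337 with 6 h and 12 h alone. The interaction gave 11318 without 1 h and 11889 with 6 h and 12 h alone. Between genotypes under ABA the count was 10606, 465, 38 and 1261 without 1, 3, 6 or 12 h and 9064 with 6 h and 12 h alone. In each fit with single arrays left out fewer arrays enter, and what made counts grow without 1 h was not tested. Leaving out 1 replicate gave 161 to 697 for 1 µM ABA, 2126 to 5508 for ppabi1a, 1386 to 2289 for ppabi1b, 887 to 1461 between these, 1203 to 1745 for 10 µM in ppabi1a/b and 0 to 10651 between the untreated sets (limma, 4311 to 4838 at an unadjusted p under 0.05 without an array of the second set), while counts for ppabi1a/b at 0 h (9083 to 9949) and 10 µM in wild type (9080 to 9412) stayed within 1.5 times. By unadjusted p, the ppabi1b median of 0.18 for the genes that rose with 1 µM ABA lost its call with an estimated correlation (p = 0.458) and with fry (p = 0.254). The 50 calls of gene lists, without the 7 between the single disruptants, became 0 with an estimated correlation (limma's camera, 15 of the 50 at an unadjusted p under 0.05), so all rest on the preset. Under quantile normalization 44 of the 50 were kept, 5 were lost, 1 reversed, ribosomal proteins in the interaction (adjusted p = 0.00739 lower, 0.028 higher), and 12 others became called. With the replicate block 18 of 19 were kept, the lipases of the 1 µM comparison being lost (adjusted p = 0.0818), and 3 others became called: phenylpropanoid enzymes in ppabi1a/b and, with kinesins, against the sum (adjusted p = 0.0486, 0.0423 and 0.0454). Signal over background limits the rest: where a group lay below it, only a bound is known.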

Other observations

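Chosen after the data were seen was the comparison of ppabi1a with ppabi1b, also in the splits and the functional classes below.

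At 0 h the genes that rose with 1 µM ABA had medians of 1.25, 0.17 and 2.12 in ppabi1a, ppabi1b and ppabi1a/b with the list without slide 1, and 0.84, 0.17 and 1.61 with the replicate block.

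Of 24 KOG functional classes, translation was called lower in ppabi1a against wild type at 0 h (103 of 811 lower, 7 higher; 50 and 5 adjusted over the list alone, median −0.11, adjusted p = 0.000443, and adjusted p = 0.881 with an estimated correlation). Against ppabi1b it was lower too (30 of 812 lower, 2 higher; 4 and 1 adjusted over the list alone, adjusted p = 3.58e-07), with chromatin (7 of 209 lower, adjusted p = 0.037), RNA processing (22 of 517 lower, 5 higher, adjusted p = 0.037) and cell cycle (6 of 173 lower, 2 higher, adjusted p = 0.0468), each with adjusted p = 0.837 with an estimated correlation. In the second untreated wild-type set signal transduction (111 of 976 higher, 32 lower, adjusted p = 0.000949) and lipid transport (32 of 400 higher, 10 lower, adjusted p = 0.00514) were higher and RNA processing (70 of 511 lower, 16 higher, adjusted p = 0.00227), translation (62 lower, 8 higher, adjusted p = 0.00343) and replication (15 of 217 lower, 3 higher, adjusted p = 0.0272) lower, none called with an estimated correlation (adjusted p = 0.328 with an estimated correlation at the lowest). No class was called in the other 8 comparisons.

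Other splits of the same arrays were counted. In the 6 comparisons of 3 against 3 arrays, 1 of 10 splits, the real one, gave as many calls, but 10 splits are too few for a share under 0.05: 651 against a highest other of 0 for 1 µM ABA, 3775 and 0 for ppabi1a, 3336 and 0 for ppabi1b, 10541 and 0 for ppabi1a/b, 2336 and 0 between the untreated sets and 1668 and 61 between the single disruptants, with limma. For 1 µM ABA, ppabi1b and ppabi1a/b, whose arrays pair, 4 splits part all pairs. Between genotypes under ABA, fitted in pairs, 8 splits part all pairs and are too few for a share under 0.05 (1 of 8; 5609 against 0). With 35 splits a chance division was excluded for 10 µM ABA in wild type (1 of 35, 10996 against 10537) and ppabi1a/b (1 of 35, 2887 against 2547), but not slide. In both, the highest other split put the 1 h array with 0 h. The 100 splits for ppabi1a/b against the sum (1 of 100, 6440 against 4440) and the interaction (1 of 100, 7403 against 2682) ignored pairs. They also mixed groups that differ, so they decide neither.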
